A study of Mus musculus with 8 samples.

How the data were processed

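The samples were mouse ventricles at postnatal day 7, and per the labels' protocols total RNA was extracted with a Direct-zol kit, treated with DNase I and made into stranded total RNA libraries. Groups were taken from the labels: wild type with 2 samples, double mutant with 3 and triple mutant with 3. A prefix in the sample descriptions takes 2 values that occur in each group, but without values per sample it could not enter any test. The labels do not say how many libraries of each group entered the authors' test, nor the sex of the pups. The p-values are those of the authors' Cuffdiff test on the libraries they entered, and the spread between samples could not be computed here.

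Reads were handled with CASAVA 1.8, STAR 2.5.2, Cufflinks 2.2.1 and Cuffdiff 2.2.1 on the mm9 build, per the submitters' processing notes. The annotation and the normalization settings are not given in the sources used here. The authors deposited gene-level output of Cuffdiff for 37982 genes and 3 comparisons. It gives 1 FPKM per gene and group, with the log2 fold change, a test score (the Cuffdiff statistic), p-value and q-value of each comparison made by the authors. FPKM is relative to transcript length and library size, so total depth is not kept and no depth per sample can be given. The sum of FPKM was 331702 in wild type, 334141 in the double mutant and 322951 in the triple mutant.

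The deposited columns were tested for how they were made. The deposited log2 fold change equals the log2 of the ratio of the group FPKM values, with no pseudocount (largest difference 4.7215e-05). The deposited q-values equal a Benjamini-Hochberg adjustment over the tested rows of all 3 comparisons together (largest difference 5.26442e-07). The lowest p-value in the file is 5e-05 and the lowest q-value 0.0066, so many genes tie there. The authors' own mark of significance falls at a q-value of 0.1, and a threshold of 0.05 was used here. Rows that the file marks as having too many fragments hold 0 as a failed estimate: 2036 rows of 709 genes, among them many sarcomere genes and the mitochondrial genome. Such genes are said to be listed at 0, with no fold change. Loci in the file start from 0, since end minus start equals the gene span of GENCODE M21 in 42.5% of the genes matched by Ensembl ID and end minus start plus 1 in 1.01%, so coordinates are given as start plus 1, in mm9. GENCODE M21 was used for this check of gene spans and for transcript length and gene type by Ensembl ID (32914 of 37982 genes matched). The coordinates printed are those of the file. A locus that the file lists with the same coordinates for another gene is called shared, because the counting could have split or joined its reads. Overlaps between loci with different coordinates were not looked for.

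With no values per sample, no new test across samples was run, and the authors' q-values are the main result, as fixed before the data were examined. The tested genes numbered 12986, 12786 and 13034 in the comparisons of triple mutant with wild type, triple with double mutant and double mutant with wild type. Gene lists were fixed before the data were examined, 33 in all. A list with at least 5 tested members was tested two-sided with cameraPR of limma 3.58.1 in R 4.3.3, on a signed z made from the deposited p-value and the sign of the log2 fold change. The preset correlation between genes was 0.01, and the 78 list tests were adjusted together by Benjamini-Hochberg, with 23 past the threshold of 0.05. None of these 23 had a median opposite to its test. Counts adjusted over the list alone apply Benjamini-Hochberg to the deposited p-values of the list's members.

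Named genes followed a rule written before the data were examined. Per comparison it takes the 8 largest rises and 8 largest falls past the threshold, with an FPKM of at least 1 in either group and above 0 in both. It adds the 2 largest rises and falls past the threshold in each list, the 3 mutated genes, and up to 4 members per list with the highest FPKM. It took 34 genes for triple mutant against wild type, 30 for triple against double and 41 for double against wild type, of which 1 gene is not reported here. Cma1, Srgn and the remaining mast cell genes were chosen after their values were seen, as were the genes called in both comparisons with the triple mutant.

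Standard errors implied by the authors' statistics (median 0.223 to 0.224 on the log2 scale) were used to simulate unchanged groups in 100 draws. This simulation was restricted to the 12316 of 12399 genes at an FPKM of 1 or more in all groups after a run over all genes gave a covariance set by a few low genes. The methods were tested on simulated data for 12399 genes with independent noise between genes. There the q-values were adjusted within each comparison, unlike the deposited ones. A q-value under 0.05 recovered 29.0% of genes changed 1.5-fold and 64.0% of genes changed 2-fold for triple mutant against wild type, 21.4% and 59.0% for triple against double, and 28.0% and 62.6% for double against wild type. Unchanged genes were called at 0.0575%, 0.00822% and 0.0247%. The cell cycle list, with every member shifted equally, was called in all 3 comparisons, which the run required in order to go on. None of the 75 tests of unshifted lists was called. With noise independent between genes, this does not show how often lists of correlated genes are called falsely.

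Alternatives were thresholds of 0.01 and 0.1, FPKM minimums of 1 and 5 (for the calls together with adjustment of the q values over the kept genes of a comparison), adjustment within a comparison alone, a minimum of 1.5-fold, centring, 1 row per symbol, a preset correlation of 0.05, ranks at a pseudocount of 1, and 10000 random lists matched on FPKM. Leaving out chromosomes X and Y, leaving out shared loci, and recounting the calls shared by both triple mutant comparisons after adjustment within each were added after the data were seen. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.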

Results

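RNA was sequenced from the ventricles of C57BL/6 mouse pups at postnatal day 7, after the atria had been trimmed off. The labels give 8 samples in 3 genotype groups: 2 wild type, 3 double mutant and 3 triple mutant. The double mutants carried altered Mkl2 and Myh7, as known from the study, and the triple mutants carried altered Nkx2-5 in addition. Mkl2 encodes a myocardin-related coactivator of serum response factor, Myh7 the beta myosin heavy chain, and Nkx2-5 a homeodomain transcription factor of heart muscle. The values used here are 1 FPKM per gene and group, so they carry no replicate error of their own, and the read depth is unknown. Of the genes listed, 13775 reached an FPKM of 1 or more in wild type, 13588 in the double mutant and 13619 in the triple mutant. Differences are called from the authors' test at a q value under 0.05.

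The mutated genes themselves were measured first, although an allele need not change its transcript level, so this does not check the labels. Nkx2-5 (ENSMUSG00000015579, mm9 chromosome 17, 26975609 to 26978510) was listed in the authors' deposited table at an FPKM of 43.6 in wild type, 53.1 in the double mutant and 55.2 in the triple mutant. Its q value there was 0.284 for the triple mutant against wild type and 0.955 against the double mutant, so neither difference passed. Mkl2 (chromosome 16, 13256574 to 13417622, a shared locus) stood at 30.9, 30.6 and 26.0 in the authors' deposited table, in the same order of groups. None of its comparisons passed, with q values in the authors' deposited table of 0.994 for the double mutant against wild type, 0.877 for triple against double and 0.879 for triple against wild type. Myh7 (chromosome 14, 55589525 to 55613471) is listed at 0 in every group of the authors' deposited table, under a status that marks too many fragments for an estimate, so its level was not measured.

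The comparison of triple mutant with wild type asks which genes are regulated differently in the hearts that model the disease. Among the largest rises in the authors' deposited table were Spp1 (7.52-fold), which encodes the secreted matrix protein osteopontin, and Lars2 (4.18-fold), the mitochondrial leucyl-tRNA synthetase, each at q = 0.0066. The mast cell proteases Cpa3 (4.63-fold, q = 0.0066) and Mcpt4 (4.13-fold, q = 0.015) and the neutrophil calprotectin subunit S100a9 (3.40-fold, q = 0.0066) rose as well in the authors' deposited table. Of these genes, Spp1 and Mcpt4 lie under the alternative FPKM minimum of 5, so their folds rest on low levels. Nuclear-encoded respiratory chain genes rose as a group by a median log2 fold change of 0.26, and endothelial markers fell by a median of 0.33 on that scale.

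In all, 198 of 12986 genes tested were called, 151 of them higher and 47 lower in the triple mutant. The median change was 1.58-fold among the higher calls and 1.63-fold among the lower calls. The other 3 of the 8 largest rises in the authors' deposited table were Cpxm1, a carboxypeptidase-like protein (3.39-fold, q = 0.0271), and the unnamed loci 2610035D17Rik (2.84-fold, q = 0.0356) and, in a shared locus, Gm7324 (2.68-fold, q = 0.0066). Among the 8 largest falls were the lysine methyltransferase Smyd3 (3.56-fold lower, q = 0.0066) and the Hedgehog pathway transcription factor Gli2 (2.79-fold lower, q = 0.0244) in the authors' deposited table. Rad51l1, a recombination repair gene (2.34-fold lower, q = 0.0114), and Gm4169 (2.25-fold lower, q = 0.0066) also fell in the authors' deposited table. Falls were also listed in the authors' deposited table for Cacnb4 (6.74-fold), Phactr1 (3.96-fold), A630001G21Rik (3.95-fold) and Tes (2.31-fold). Their loci are shared with other genes, so these values are uncertain. Cpxm1, 2610035D17Rik, Gm7324, Rad51l1 and A630001G21Rik lie under the alternative FPKM minimum, so their folds rest on low levels too.

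Of 32 tested nuclear-encoded respiratory chain genes, 4 were called higher and none lower, and 10 rose when adjusted over the list alone. In the authors' deposited table the cytochrome oxidase subunit Cox5a rose from an FPKM of 86.6 to 149 (q = 0.0184, in a shared locus), and Ndufa4 rose from 36.8 to 59.9 (q = 0.0184). The list passed the competitive test (limma cameraPR, adjusted p = 1.7e-09). An estimated correlation between genes needs values per sample, so none was fitted, and the list tests used a preset correlation of 0.01. The list tests take genes as their units, so their p values do not measure how far a list varied between pups. In the same comparison short transcripts stood higher: the median log2 fold change was 0.09 in the shortest of 8 length bins and -0.07 in the longest. The Y-linked genes differed as well, with a median log2 fold change of 1.05 over 4 genes, and Ddx3y rose 2.08-fold in the authors' deposited table (q = 0.0066). With the sex of the pups not given, sex and genotype cannot be separated between these groups.

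The fetal and stress programme of cardiomyocytes rose (13 tested, median 0.35, adjusted p = 0.0026 by cameraPR), with 2 members called over all genes and 2 when adjusted over the list alone. These were Ankrd1, a stress-responsive ankyrin repeat protein (1.55-fold, q = 0.015), and Tnni1, the slow troponin I isoform of the fetal heart (1.57-fold, q = 0.0066), in the authors' deposited table. Nppa, the atrial natriuretic peptide gene, whose locus is shared, stood at 919 in wild type and 829 in the triple mutant in the authors' deposited table (q = 0.831). Of the 22 sarcomere genes 16 are listed at 0, and among the 6 tested the Z-disc gene Synpo2l rose 1.64-fold in the authors' deposited table (q = 0.0066). That list had a median of 0.28 and 3 genes higher when adjusted over the list alone (cameraPR adjusted p = 0.0031). The call was lost on ranks (adjusted p = 0.094) and among random lists matched on FPKM (rank of 93.2%).

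Endothelial markers were lower in 15 of 16 genes, yet no single member was called, over all genes or adjusted over the list alone (cameraPR adjusted p = 2.8e-06). The junction gene Cdh5 stood at 204 and 188 and the adhesion gene Pecam1 at 172 and 144 in the authors' deposited table, in wild type and triple mutant. Extracellular matrix genes fell with a median of -0.16 (28 tested, cameraPR adjusted p = 0.0049), with 1 member higher and 1 lower over all genes, and 1 and 5 when adjusted over the list alone. That call was lost at a preset correlation of 0.05 (adjusted p = 0.068) and on ranks (adjusted p = 0.061). The higher member was Spp1, and the lower was the elastin gene Eln, which fell 1.84-fold in the authors' deposited table (q = 0.015).

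Cell cycle genes were higher by a median of 0.21 with none of 31 called, over all genes or adjusted over the list alone (cameraPR adjusted p = 0.0029, but 0.054 at a preset correlation of 0.05). Immediate early genes rose by a median of 0.18 (20 tested, adjusted p = 0.0055, but 0.054 at a correlation of 0.05 and 0.056 on ranks), with 1 call over all genes and 1 adjusted over the list alone, the antiproliferative gene Btg2 (1.42-fold in the authors' deposited table, q = 0.0297). Heat shock genes rose by a median of 0.22 (9 tested, adjusted p = 0.017, but 0.054 at a correlation of 0.05 and 0.12 on ranks), with 1 call over all genes and 1 adjusted over the list alone, the small chaperone Hspb1 (1.57-fold in the authors' deposited table, q = 0.0066). Glycolysis genes rose by a median of 0.17 (19 tested, adjusted p = 0.024, but 0.12 at a correlation of 0.05 and 0.16 on ranks), with 2 calls over all genes and 3 adjusted over the list alone. In the authors' deposited table these included the muscle mutase Pgam2 (1.45-fold, q = 0.015) and the pyruvate kinase Pkm2 (1.43-fold, q = 0.0458). Genes of the integrated stress and unfolded protein response rose by a median of 0.12 (20 tested, adjusted p = 0.027, but 0.13 at a correlation of 0.05 and 0.32 on ranks), with 2 calls over all genes and 4 adjusted over the list alone. The calls were the endoplasmic reticulum chaperones Calr (1.43-fold, q = 0.0458) and Pdia4 (1.56-fold, q = 0.0066, in a shared locus) in the authors' deposited table. Each of these 5 list calls was thus lost at a correlation of 0.05, and the heat shock, glycolysis and stress response calls were lost also among random lists matched on FPKM (ranks of 92.2%, 94.7% and 91.65%).

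Outside these lists, the conduction system factor Irx3 (1.57-fold, q = 0.0066, in a shared locus) and Tbx5 (1.41-fold, q = 0.044) rose in the authors' deposited table. Of 23 tested fatty acid oxidation genes, 3 were called higher and 1 lower, and 4 and 2 when adjusted over the list alone. The list did not pass (cameraPR adjusted p = 0.24). The calls included Etfb, a subunit of the electron transfer flavoprotein (1.45-fold higher, q = 0.0066), and the nuclear receptor Ppara (1.67-fold lower, q = 0.0244) in the authors' deposited table. The calls of Cacnb4, Tbx5, Pkm2 and Calr were lost when q values were recomputed within this comparison (q of 0.0535 for Tbx5 and 0.0541 for the other 3).

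The comparison of triple with double mutant asks what changes when the Nkx2-5 modifier is present. Cell cycle genes rose together in the triple mutant by a median log2 fold change of 0.55. The mitotic cyclin Ccnb1 rose from an FPKM of 17.6 to 31.4 (q = 0.0066) and the spindle motor Kif11 from 11.2 to 18.2 (q = 0.0066) in the authors' deposited table. The natriuretic peptide gene Nppa rose 1.64-fold and Bmp7, a bone morphogenetic protein, 1.96-fold, each at q = 0.0066 in the authors' deposited table. Fibroblast markers fell by a median of 0.27 and endothelial markers by a median of 0.23 on the log2 scale.

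In all, 160 of 12786 genes tested were called, 90 higher and 70 lower in the triple mutant, with median changes of 1.59-fold and 1.54-fold. After Xist, the X inactivation RNA (1.21 in the double and 88.2 in the triple mutant, in a shared locus), the largest rise in the authors' deposited table was Spp1 (12.8-fold), followed by Lars2 (7.73-fold), each at q = 0.0066. The replication genes Cdc6 (2.24-fold, q = 0.0066) and Prim1 (2.27-fold, q = 0.0214) rose, as did 8430419K02Rik (2.91-fold, q = 0.0066), in the authors' deposited table. Lrp8 (4.31-fold higher), the centromere gene Cenpt (2.75-fold higher), Slc15a2 (6.46-fold lower) and the neurotrophic receptor gene Gfra1 (2.34-fold lower) were called at q = 0.0066 in the authors' deposited table, in loci shared with other genes. Falls in single loci of the authors' deposited table included 2210408F21Rik (4.09-fold, q = 0.0184), the small RNA Scarna13 (2.40-fold, q = 0.0066), Rtn4r (2.28-fold, q = 0.015), the lymphocyte antigen gene Ly6e (2.21-fold, q = 0.0066) and Scara5 (2.17-fold, q = 0.0066). Asb15 also fell 2.16-fold in the authors' deposited table (q = 0.0066), in a shared locus. In this comparison Spp1, Cdc6, Prim1, Lrp8, Cenpt, Slc15a2, Gfra1 and Scara5 lie under the alternative FPKM minimum, so their folds rest on low levels.

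Every one of the 31 tested cell cycle genes had a positive log2 fold change, 8 were called over all genes and 19 when adjusted over the list alone (cameraPR adjusted p = 1.4e-27, and 3.0e-14 at a correlation of 0.05). These p values reflect agreement among genes and not how far the list varied between pups, which could not be measured. Ccna2 rose 1.54-fold (q = 0.0244, in a shared locus) and the ribonucleotide reductase subunit Rrm2 1.47-fold (q = 0.0321) in the authors' deposited table. The topoisomerase gene Top2a stood at 57.0 in the double and 84.7 in the triple mutant in the authors' deposited table (q = 0.238). The fetal and stress programme rose by a median of 0.22 (13 tested, adjusted p = 4.2e-04), with 3 calls over all genes and 3 adjusted over the list alone. These were Nppa, the smooth muscle actin Acta2 (1.5-fold, q = 0.0066) and Ankrd1 (1.49-fold, q = 0.0271) in the authors' deposited table. Targets of serum response factor and its myocardin-related cofactors rose by a median of 0.22 (19 tested, adjusted p = 0.0011), with Acta2 and Ankrd1 as the 2 calls over all genes and 4 adjusted over the list alone. The interferon response list had a median of 0.20 (14 tested, none called over all genes and 1 adjusted over the list alone, adjusted p = 0.044). That call was lost at a preset correlation of 0.05 (adjusted p = 0.14), on ranks (adjusted p = 0.12) and among random lists matched on FPKM (rank of 96.6%).

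None of the 11 tested fibroblast markers was called over all genes and 2 fell when adjusted over the list alone (cameraPR adjusted p = 6.2e-05). Col1a1, the collagen I alpha chain gene, stood at 218 in the double and 163 in the triple mutant in the authors' deposited table (q = 0.157). Of 16 endothelial markers the water channel gene Aqp1 was called, 1.40-fold lower in the authors' deposited table (q = 0.0342), and 3 fell when adjusted over the list alone (adjusted p = 1.3e-04). Ion channel and calcium handling genes fell by a median of 0.13 (15 tested, adjusted p = 0.0024, but a rank of 3.6% among random lists matched on FPKM, where the call was lost), with 1 call over all genes and 3 adjusted over the list alone. That call was the potassium channel subunit Kcnip2, 1.48-fold lower in the authors' deposited table (q = 0.0066). Respiratory chain genes had a median of -0.11 (32 tested, adjusted p = 0.011, but 0.12 at a correlation of 0.05 and a rank of 2.5% among random lists, where the call was lost), with 1 call over all genes and 1 adjusted over the list alone, Cox8b, which fell 1.58-fold in the authors' deposited table (q = 0.0066).

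Calls in other lists included Tgfb1 (1.62-fold lower, q = 0.0184), the pericyte channel gene Kcnj8 (1.5-fold lower, q = 0.0114), Nr4a1 (1.45-fold lower, q = 0.0321), Klf4 (1.38-fold lower, q = 0.0418) and S100a9 (1.95-fold higher, q = 0.0244) in the authors' deposited table. Recomputed within this comparison, q was 0.0503 for Aqp1 and 0.0622 for Klf4, which ended both calls. The median of the 4 Y-linked genes was -0.48 in this comparison.

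The design text does not name the comparison of double mutant with wild type, but the 3 groups imply it. Respiratory chain genes rose by a median log2 fold change of 0.37, the largest median among the 5 lists past the threshold here. In the authors' deposited table Ndufa4 rose from an FPKM of 36.8 to 83.4, Cox5b from 14.7 to 32.6 and Cox8b from 848 to 1666, each at q = 0.0066. Cell cycle genes fell by a median of 0.33, and Nppa fell 1.82-fold in the authors' deposited table (q = 0.0066). The Y-linked genes differed most here, with a median log2 fold change of 1.53, and Ddx3y (2.90-fold) and Uty (2.71-fold) rose in the authors' deposited table, each at q = 0.0066. The sex of the pups is not given, so sex and genotype cannot be separated in this comparison either.

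In all, 346 of 13034 genes tested were called, 246 higher and 100 lower in the double mutant, with median changes of 1.61-fold and 1.75-fold. The largest rises in single loci of the authors' deposited table were Cpxm1 (4.37-fold), Cpa3 (3.75-fold), Trappc1 (3.16-fold), which encodes a vesicle tethering subunit, and 2610035D17Rik (3.16-fold), each at q = 0.0066. Ctf1, the cardiotrophin 1 gene, was 4.99-fold higher (q = 0.0418, in a shared locus), Gm10146 2.95-fold (q = 0.0321) and Hrasls 2.91-fold (q = 0.0458) in the authors' deposited table. Tmem91 (4.79-fold, q = 0.0271), Gm4169 (4.07-fold, q = 0.0066), Rad51l1 (3.94-fold, q = 0.0066), 4833412C05Rik (3.39-fold, q = 0.0321) and 4921513I03Rik (3.08-fold, q = 0.0342) fell in the authors' deposited table. Gm4070 (3.42-fold, q = 0.0297), the translational regulator Cpeb1 (3.29-fold, q = 0.0342) and the lysosomal mannosidase Manba (3.02-fold, q = 0.015) fell in the authors' deposited table, in shared loci. In this comparison Cpxm1, Cpa3, 2610035D17Rik, Ctf1, Hrasls, Tmem91, Rad51l1 and 4921513I03Rik lie under the alternative FPKM minimum, so their folds rest on low levels.

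Of 32 tested respiratory chain genes, 8 were called higher and none lower, and 16 rose when adjusted over the list alone (cameraPR adjusted p = 1.9e-12). Short transcripts stood higher here too, with a median log2 fold change of 0.11 in the shortest of 8 length bins and -0.10 in the longest. Fatty acid oxidation genes had a median of 0.20 (23 tested, adjusted p = 0.034, but 0.16 at a preset correlation of 0.05, 0.18 on ranks and a rank of 94.1% among random lists matched on FPKM, where the call was lost). Of these 5 were called higher and 1 lower over all genes, and 7 and 2 when adjusted over the list alone. They included Etfb (1.69-fold higher) and Pdk4, which restrains pyruvate oxidation (1.48-fold lower), each at q = 0.0066 in the authors' deposited table. The sarcomere list had a median of 0.35 over 6 tested genes (adjusted p = 0.0031, but a rank of 94.2% among random lists matched on FPKM, where the call was lost), with 1 call, Synpo2l (1.46-fold in the authors' deposited table, q = 0.0184), and 3 higher when adjusted over the list alone.

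Of 32 tested cell cycle genes 30 were lower, 1 was called over all genes and 8 fell when adjusted over the list alone (cameraPR adjusted p = 2.7e-08). The call was Rrm2, which fell 1.45-fold in the authors' deposited table (q = 0.0356). Immediate early genes rose by a median of 0.36 (20 tested, adjusted p = 1.2e-04), with 3 calls over all genes and 8 adjusted over the list alone. Btg2 rose 1.66-fold and Jun, an AP-1 subunit, 1.55-fold, each at q = 0.0066 in the authors' deposited table, the latter in a shared locus. Calls in other lists of the authors' deposited table included Eln (2.06-fold lower), Tnc (1.70-fold lower, in a shared locus), Bmp7 (1.66-fold lower), Col6a1 (1.56-fold higher), the epicardial gene Aldh1a2 (1.57-fold higher), Dnajb9 (1.53-fold higher), Hspb1 (1.67-fold higher) and Pgam2 (1.74-fold higher), each at q = 0.0066. Kcnip2 rose 1.47-fold (q = 0.0114), Bag3 1.37-fold (q = 0.0496), Pdia4 1.45-fold (q = 0.015, in a shared locus) and Tpi1 1.76-fold (q = 0.0271, in a shared locus) in the authors' deposited table.

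**Figure D1:**
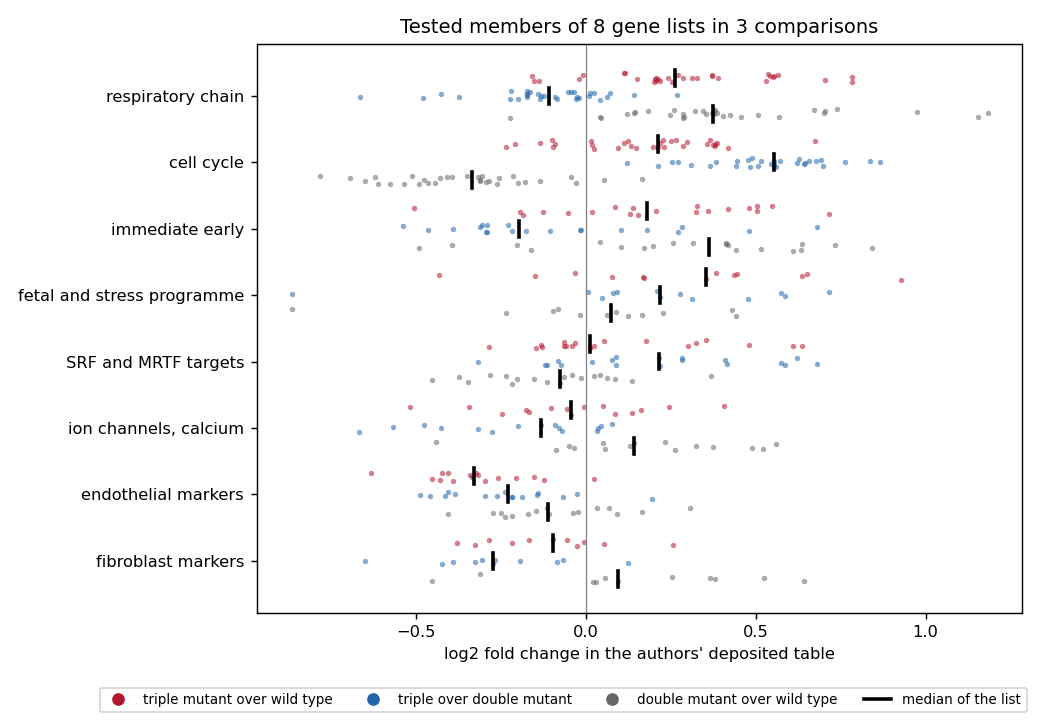
Each point is a tested gene of the list named on the vertical axis, the horizontal axis is its log2 fold change in the authors' deposited table, and black bars are list medians. Respiratory chain medians lie at 0.26 for triple mutant over wild type and 0.37 for double mutant over wild type, and the cell cycle medians at 0.55 for triple over double and -0.33 for double over wild type.

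The lists that passed in no comparison were 11 of those tested, with adjusted p values between 0.0901 and 0.946. They covered cardiac transcription factors, trabecular and conduction genes, compact myocardium, Notch, BMP and neuregulin signalling, sex-linked genes, and markers of atrial, endocardial, epicardial, smooth muscle, macrophage and erythroid cells. The sex-linked list mixes Y-linked and X-linked genes, so opposite changes can cancel in its test. In double mutant against wild type 4 of its members were higher and 3 lower, with a median of 1.44 and 2 calls. Its test therefore does not show that sex-linked genes were alike. A further 7 lists had too few tested members: mitochondrially encoded genes, all 9 listed at 0, and markers of neutrophils and lymphocytes, Schwann cells, adipocytes, skeletal muscle, lung, and thymus and liver.

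The triple mutant enters both named comparisons, and 18 genes were called in both. Of these 12 were higher in the triple mutant in both and 4 lower in both, while independent lists would share 1.07 and 0.239. With q values recomputed within each comparison, a recount chosen after the data were seen, 13 remained, 9 higher and 2 lower in both, and Ywhae, Stmn1, Iigp1, Sod3 and AC027184.1 lost their call in triple against double mutant (recomputed q of 0.0622 to 0.0673). These 18 were named after their values were seen, apart from Spp1, Lars2, S100a9, Ankrd1 and Trappc1. Higher against both other groups were the mitotic genes Hmmr (1.61-fold over wild type and 1.82-fold over the double mutant) and Cdca3 (1.61-fold and 1.8-fold) in the authors' deposited table. The tubulin gene Tuba1b (1.5-fold and 1.55-fold) and the insulin-degrading enzyme Ide (1.64-fold and 1.60-fold, in a shared locus) were also higher against both in the authors' deposited table. The microtubule genes Stmn1 (1.59-fold and 1.42-fold) and Haus3 (1.42-fold and 1.47-fold), the adaptor gene Ywhae (2.2-fold and 1.60-fold) and the interferon-inducible GTPase Iigp1 (2.2-fold and 1.51-fold) followed in the authors' deposited table, all but Iigp1 in shared loci. Lower against both were the anticoagulant receptor Thbd (1.42-fold and 1.57-fold), the extracellular dismutase Sod3 (1.65-fold and 1.64-fold), Tnxb (1.49-fold and 1.40-fold, in a shared locus) and AC027184.1 (1.59-fold and 1.41-fold) in the authors' deposited table. Trappc1 and Zbtb16 were called in opposite directions. Sod3 lies under the alternative FPKM minimum in both comparisons, so its folds rest on low levels.

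Because both comparisons use the triple mutant libraries, unchanged groups were simulated from the errors that the authors' statistics imply. In 100 draws no gene was called in both. Unchanged genes rarely pass this threshold at all, so that 0 does not show how many calls shared libraries would carry into both lists. At p under 0.05, 220 genes moved in the same direction in both, against 116 in the simulated groups, and 48 moved in opposite directions, against 0.15. The covariance of the fold changes was 0.0330, below the simulated 0.105, a difference of -0.0718, so it gives no estimate of a shared effect. The libraries cannot be split without values per sample, so part of the excess may come from the shared libraries. The double mutant comparisons shared 57 calls, all in opposite directions, where 2.03 opposite calls would come from independent lists and 0 from the simulation, with the same limit. At p under 0.05, 455 genes moved in opposite directions in them, against 118 in the simulated groups, and 7 in the same direction, against 0.14. The fold changes of the double mutant comparisons had a correlation across genes of -0.52, as in the simulated unchanged groups (-0.52). They had a covariance of -0.0628 beside the simulated -0.111, a difference of 0.0479, so neither measure gives an estimate of opposed effects. Among the 57, Ly6e went from 104 in wild type to 202 in the double mutant and 91.2 in the triple mutant, and Kcnip2 from 46.4 to 68.4 and 46.2, in the authors' deposited table. The comparisons against wild type share the wild type libraries and had 89 calls in common, 74 higher in both, 14 lower in both and 1 in opposite directions. Independent lists would share 2.82 and 0.367, and the simulation gave 0, with the same limit. At p under 0.05, 732 genes moved in the same direction in both, against 113 in the simulated groups, and 9 in opposite directions, against 0.24. The fold changes of the comparisons against wild type had a correlation across genes of 0.652 beside 0.479 in the simulated groups. The covariance was 0.0883 beside the simulated 0.0991, a difference of -0.0108, so it gives no estimate of a shared effect, and part of the overlap may come from the shared libraries.

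**Figure D2:**
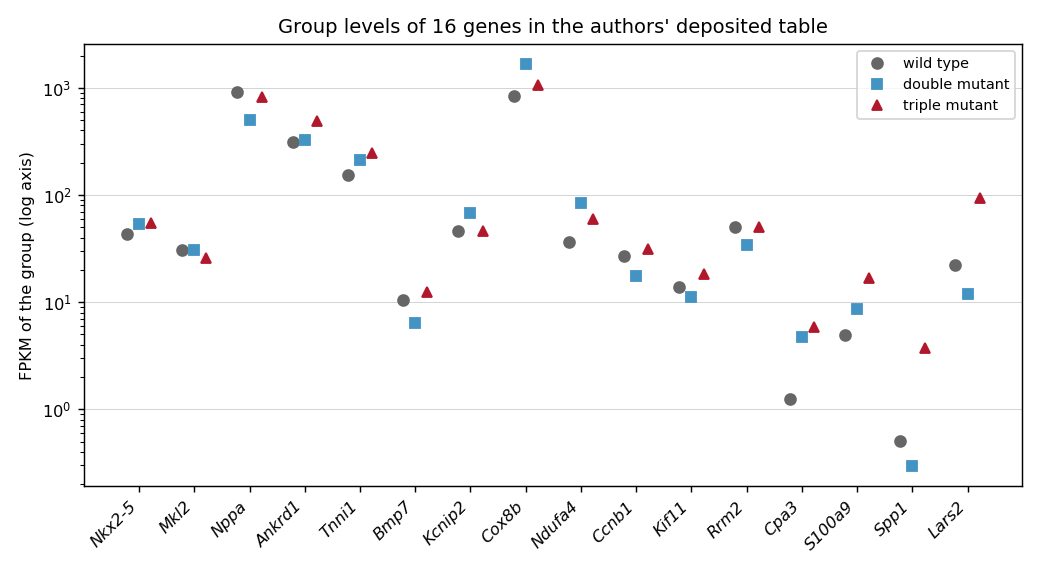
Points are the group FPKM of 16 genes in the authors' deposited table on a log axis, with circles for wild type, squares for the double mutant and triangles for the triple mutant. There are no error bars because the table holds 1 value per group, as for Lars2 at 22.2, 12 and 92.8.

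**Figure D3:**
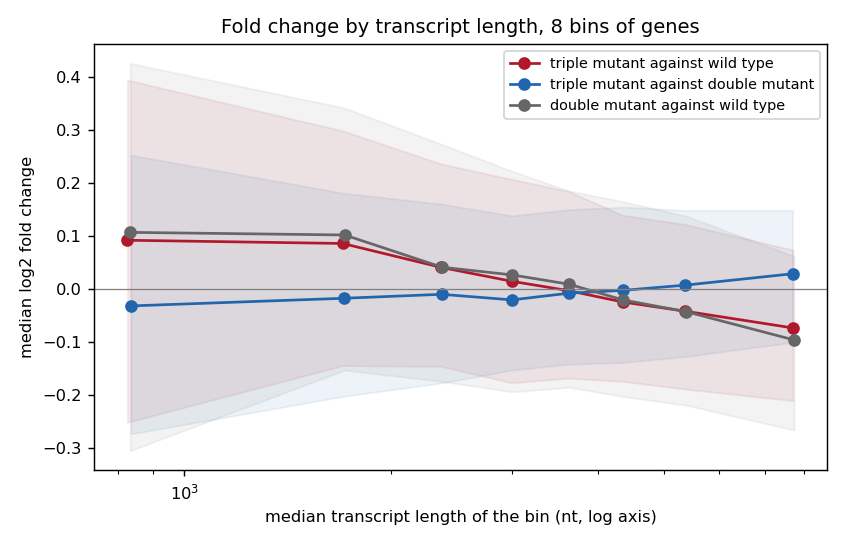
Lines are median log2 fold changes of genes in 8 bins of transcript length (horizontal log axis, in nt), with shading for the quartiles of each bin. Both comparisons against wild type go down with length, from 0.09 to -0.07 for the triple and from 0.11 to -0.10 for the double mutant, and triple against double goes from -0.03 to 0.03.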

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

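The tests of transcript length by removal of the trend were planned, and all the other tests here were chosen after the result was seen, including the second rank for length, the removal of the length trend from the muscle comparison, the bootstrap conditions and the condition at a preset correlation of 0.05. The conditions were tightened after first results, which had excluded the muscle explanation, the sex explanation of the cell cycle genes and both mast cell explanations. The cell cycle and respiratory chain lists and the single genes from Lars2 to Scarna13 were picked out because the double mutant against wild type and the triple against the double mutant were both called, in opposite directions. The mast cell genes were not picked in that way: they were chosen after their values were seen, and no list test was run on them. The opposed comparisons share the double mutant libraries, so an error in those libraries gives this pattern too.

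The cell cycle list had a median log2 fold change of 0.55 in the triple against the double mutant and -0.33 in the double mutant against wild type. A transcript length trend would leave the list inside random lists of like FPKM, yet its median ranked at 100% of 10000 lists both after removal of the trend and beside lists matched on length. A larger share of non-muscle cells would raise their markers, but 46 markers had a median of -0.21 (bootstrap 95% range -0.26 to -0.14), against 0.48 to 0.62 for the cell cycle list. These 46 were endothelial, fibroblast, smooth muscle, pericyte and macrophage markers, so the values speak only to those cells. Epicardial, neutrophil and lymphocyte markers were not in this pool. A different share of male and female pups stays open: the triple mutant lies between the others in Y-linked genes and above both in the cell cycle list, which goes against it (median against wild type 0.21, bootstrap 95% range over genes 0.11 to 0.27, adjusted p of 0.00293 and 0.0175 on ranks, and a rank of 99.98% among random lists matched on FPKM), but the adjusted p became 0.0545 at a preset correlation of 0.05, and no values per sample show how far these genes vary together. With sex open, an effect of the Nkx2-5 allele remains a possible explanation that these values cannot separate from the sex of the pups.

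Respiratory chain genes were higher in both mutant groups and had a median of -0.11 in triple against double mutant (a call lost at a preset correlation of 0.05, adjusted p = 0.12, and among random lists matched on FPKM), and against wild type short transcripts were also higher (Spearman correlation across genes, which are not independent, of -0.148 for triple and -0.168 for double mutant against wild type). Removal of the trend took the list median from 0.26 to 0.20 in the triple and from 0.37 to 0.26 in the double mutant, and random lists matched on both FPKM and length had medians of 0.15 and 0.19. The lower of the ranks among random lists was 98.05%, which argues only weakly against length as the whole cause. Random lists draw each gene separately, so they do not carry the correlation between genes of this list. A larger share of heart muscle cells cannot be told apart: the list exceeded 21 other muscle genes by a two-sided permutation p of 0.00667 and 0.0387, but after removal of the length trend by 0.0124 and 0.794. The sex of the pups cannot be told apart either, because the groups rank alike by this list and by Y-linked genes, whose median was 1.53 in the double mutant against wild type, and the mutant alleles remain an untested biological explanation.

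Of 20 mast cell genes listed after the values were seen, 17 stood above wild type in the triple and 15 in the double mutant, among them Cpa3 on chromosome 3 and, near Myh7 on chromosome 14, Mcpt4 (called in the triple mutant only) and Cma1, the last at 3.18, 8.55 and 8.39 in wild type, double and triple mutant in the authors' deposited table. Srgn on chromosome 10 stood at 8.87, 18.5 and 13.7 in the authors' deposited table. For an effect of the Myh7 locus, 17 mast cell genes on other chromosomes, 15 above 0 in the triple and 12 in the double mutant, had a median log2 ratio at a pseudocount of 0.1 of 0.63 and 0.57, with bootstrap 95% ranges of 0.49 to 1.42 and 0 to 1.05. For a general rise of blood-derived cells, macrophage and erythroid markers had medians of 0.08 and 0.26. The range of their difference from 0.5 times the mast cell median ended at -0.07 in the triple and at 0.22 in the double mutant. The first value goes against an equal rise of macrophage and erythroid cells in the triple mutant only. Neutrophil and lymphocyte markers, also named in the prediction, were left out of this pool. Of these, 3 were tested in triple mutant against wild type, all 3 were higher and 1 was called. In double mutant against wild type 2 were tested, 1 higher and 1 lower. A general rise thus stays open in both mutants. Many of the mast cell genes lie near the floor, so both explanations cannot be told apart from a rise of mast cells caused by the mutations.

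In the authors' deposited table Lars2 had a log2 fold change of 2.95 in the triple against the double mutant and fell by 0.89 in the double mutant against wild type. Nppa (0.72), Bmp7 (0.97), Cdc6 (1.16), Rrm2 (0.56), Zbtb16 (0.63) and 8430419K02Rik (1.54) rose in the triple against the double mutant in the authors' deposited table, on the log2 scale, after falling in the double mutant. Cox8b (-0.66), Kcnip2 (-0.57), Trappc1 (-0.73), Ly6e (-1.15), Asb15 (-1.11) and Scarna13 (-1.27) fell in the triple against the double mutant in the authors' deposited table, after rising in the double mutant.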

How the results depend on the processing

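Leaving out chromosomes X and Y, leaving out shared loci, and recounting the shared calls with q values adjusted within each comparison were chosen after the data were seen. At q thresholds of 0.01 and 0.10 the calls numbered 72 and 357 for triple mutant against wild type (198 at 0.05), 66 and 253 for triple against double (160), and 156 and 575 for double mutant against wild type (346), and the share of higher calls was 81.9% at 0.01 in the first, against 76.3%. The list tests past the threshold fell from 23 to 14 at a preset correlation of 0.05 and to 15 on ranks, where 9 and 8 were lost. Random lists matched on FPKM lost 9 and gained 9. Gained in triple against double mutant were immediate early (rank of 0.17%), Notch, BMP and neuregulin (0.66%), smooth muscle and pericyte (0.82%) and glycolysis (98.04%). Against wild type, the double mutant gained SRF and MRTF targets (2.06%), extracellular matrix (2.36%) and sex-linked genes (100%). The triple mutant gained interferon response (98.73%) and sex-linked genes (100%) there. The 18 calls shared by both comparisons with the triple mutant became 39 at a q of 0.10, 11 at 1.5-fold and 13 adjusted within each comparison. The causes were not tested beyond the stricter or looser threshold itself. No result reversed, and under the other alternatives counts moved by less than 1.5 times. Adjusted within a comparison the calls were 176, 124 and 446, and with that adjustment plus an FPKM minimum of 5, which changes 2 choices together, 185, 116 and 420, of which 180, 116 and 303 were calls before. They were at 1.5-fold or more 136, 111 and 264, without shared loci 147, 115 and 272, without chromosomes X and Y 191, 154 and 329, and with 1 entry per symbol and no small RNA 195, 157 and 344, in the order above. An FPKM minimum of 1 removed 0 tested genes, so it says nothing about low genes. Adjusted within a comparison, 11 named results lost their call and 127 did not. With the FPKM minimum of 5 added 5 lost it, each of which adjustment alone also ended, and 108 did not, while the others lie under that minimum and have no value there. Among the shared calls, those lost by adjustment within a comparison were Ywhae, Stmn1, Iigp1, Sod3 and AC027184.1 in triple against double mutant. No paired analysis was possible because the table holds 1 value per group and no value per sample. For the same reason the pseudocount fits, leaving out each replicate, the block, the batch term, the count test on recovered reads and other splits of the samples were not run. Depth is unknown. The simulated recovery of 21.4% to 29.0% of 1.5-fold changes, with q values adjusted within each comparison, limits what a missing call can show.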

Other observations

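Both tests here were chosen after the result was seen. In the authors' deposited table the macrophage gene Lyz2 stood at 8.53 in wild type, 11.7 in the double and 9.89 in the triple mutant, and the complement gene C1qa at 12.1, 13.4 and 11.1, with no call. The globin gene Hbb-b1 stood at 171, 215 and 212 in the authors' deposited table, also with no call. Among sex-linked genes of the authors' deposited table, Eif2s3y stood at 10.2, 41.1 and 31.1 and Kdm5d at 1.22, 3.49 and 2.51. Xist stood at 1.21 in the double and 88.2 in the triple mutant in the authors' deposited table. In wild type Xist is listed at 0 under the status that marks too many fragments, so this 0 is a failed estimate and not a low level. Some abundant genes have such a 0 in part of the groups in the authors' deposited table: the gap junction gene Gja1 is listed at 803, 0 and 0 and the proliferation marker Mki67 at 113, 90.9 and 0.

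A hypothesis was that linked variants or regional effects around the 3 mutated genes may add calls near them. Within 5 Mb, 6 of 365 tested genes were called in the triple mutant against wild type (1.64%, against 1.52% elsewhere) and 8 of 366 in the double mutant (2.19%, against 2.67%). The Fisher exact p, two-sided, was 0.827 and 0.740, so an excess near these genes was not detectable, and a small one is not excluded.

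Some of the named falls against wild type, such as Smyd3, Rad51l1 and Gli2, lie in genes with a long genomic span, and a lower share of unspliced RNA in the mutant libraries could lower such genes. Leaving out shared loci, the median span of the lower calls was 21.6 kb in the triple and 28.2 kb in the double mutant against wild type, beside 20.3 and 24.8 kb in random lists matched on FPKM and transcript length. Their ranks among 10000 lists were 60.0% and 78.7%, so a longer span of the lower calls was not shown. The lower calls of triple against double mutant had a median span of 7.46 kb, beside 13.2 kb in matched lists, a rank of 0.16%.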
